A study of Homo sapiens with 6 samples.

How the data were processed

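Total RNA was extracted with Trizol and treated with DNase I, and a commercial provider prepared and sequenced the libraries on an Illumina platform, per the labels' protocols. The submitters' processing notes name HISAT2, StringTie and GRCh38, without versions, roles or order. The gene annotation, read length, strandedness and any filter on reads or genes are not given in the sources used here. The deposited table holds the FPKM that the authors computed, fragment abundances scaled by transcript length and by the mapped fragments of the library and rounded to 2 decimals, for 33392 Ensembl genes in 6 columns, 1 per library, per the file headers. All 6 columns were matched to the labels by their library names, and 0 other columns of per-sample values were present. FPKM is scaled within each library, so it does not hold the sequencing depth, and a few abundant transcripts can shift all others. Genes with reads shared between paralogs, pseudogenes or overlapping antisense genes are uncertain, because strand use and the treatment of multiply mapped reads are not given in the sources used here.

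Symbols came from the table of gene names, which left 8462 identifiers without one. Libraries were grouped as the labels state, 3 with the scramble siRNA and 3 with siDYRK2, and no 2 columns were identical. Genes with a mean FPKM of at least 0.5 over the 6 libraries (15121) were tested on log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3, using moderated statistics with a mean-variance trend, no block and no other covariate, and Benjamini-Hochberg adjustment at 0.05. DYRK2 was also compared by an exact two-sided permutation test. Values are given as mean ± SD of FPKM over 3 libraries, and fold values in the text are ratios of mean FPKM.

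Gene sets were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over 19 lists. With an estimated correlation 0 of the 10 lists past the threshold remained past it, the lowest adjusted p being 0.25. Part of this loss does not come from correlation, because p also rose where the estimate was below the preset 0.01. In the proximal tubule list, with an estimate of −0.13, the unadjusted camera p rose from 0.017 to 0.073. Fry, which tests whether a list moves on balance in one direction without comparing it with other genes, was past the threshold for 13 lists. The lists were written before the data were examined and cover G2/M and mitosis, G1/S and DNA replication, p53 targets, extracellular matrix, TGF-β/SMAD targets, mesenchymal and contractile genes, epithelial junctions, proximal tubule identity, tubular injury, inflammatory and secreted factors, interferon-stimulated genes, the unfolded protein and integrated stress responses, hypoxia and glycolysis, cholesterol synthesis, endothelial and immune cells, fibroblasts and mesangium, mitochondrially encoded genes, cytosolic ribosomal proteins, and the DYRK family with the DYRK2 complex.

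Named genes followed a rule also written before the data were examined. It takes DYRK2, a fixed panel of 17 genes of the cell cycle, fibrosis and tubular injury, the 10 largest increases and the 10 largest decreases on the log2(FPKM + 0.5) scale among genes past the threshold with a mean of at least 2 FPKM, groups that do not overlap and an official symbol, and up to 4 members of each list past the threshold with the smallest adjusted p. Some genes that the rule takes are not reported here. Genes outside this rule are named as members of a small count or are described as chosen after their values were seen.

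Sequence words were counted in 1 protein-coding transcript per gene from GENCODE v29 on GRCh38, preferring the principal isoform and the longest 3′ untranslated region up to 20000 bases. Coordinates are from the same annotation. This scan was designed after the fold changes had been seen. Words of 7 bases present in at least 100 of 11636 genes with 3′ untranslated regions of at least 50 bases were regressed against the fold change, limited to ±1.5, with the logarithm of the length and the GC share and their squares as covariates, in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. In simulated data with a planted word the scan ranked that word lowest.

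To look for whole reads in the FPKM values, the values of 5468 short single-transcript genes were multiplied by transcript length. After division by the most frequent step, 23.8% to 26.9% of values per library lay within 0.1 of a whole number, against 20% by chance, so counts were not recovered and no count model was used. The depth per library is therefore unknown and no counting interval is given.

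The limma test was tested on simulated values for the siDYRK2 comparison, with 14844 genes in that step. It called 18% of genes changed by a log2 fold change of 0.25 either way, 62.5% at 0.5, 95.8% at 1 and 100% at 2, and 9 of 140 calls (6.43%) were false. The simulation held far fewer changed genes than the 5793 called in the data, so its cutoff on the unadjusted p was stricter. These shares therefore do not give the power of the real comparison, and depth was not simulated.

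Alternatives covered pseudocounts of 0.1 and 1, no filter and a filter of 2 FPKM, median-ratio scaling, quantile normalization, rescaling of each library to a common sum, no mean-variance trend, the replicate number as a block, each library left out in turn, an additional minimum absolute log2 fold change of 1, and, for lists, an estimated correlation and fry. Rescaling to a common sum of 1000000 raised all values while the filter and pseudocount stayed the same, so it also acted as lower settings of both. The alternatives with only the genes searched for ATCTAT, and with only those of them without it, were added after the data had been seen. Named genes were followed through the fits that included them, and the minimum fold change was applied only to the counts of genes.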

Results

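RNA sequencing was performed on 6 libraries of HK-2 cells, an immortalised epithelial cell line from the proximal tubule of the human kidney. All cells were stimulated with TGF-β1, a cytokine that drives extracellular matrix production and epithelial dedifferentiation in the tubule, and all carry a 48 h time point in their labels. In 3 libraries the cells had received a scramble siRNA, and in the other 3 an siRNA against DYRK2, a protein kinase of the dual-specificity tyrosine-regulated family. The study concerns DYRK2 in renal fibrosis and its link to CDK1 and the G2/M phase, so the comparison asks which transcripts differ when DYRK2 is silenced under TGF-β1. Libraries without TGF-β1 were not analysed here, so no value measures the response to the cytokine itself. The labels do not say that the 3 replicates of a group were separate cultures, so p-values measure the spread between these samples, which may be technical.

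Expression was given as FPKM for 33392 genes. The FPKM values of a library summed to between 252318 and 255378, of which the mitochondrially encoded transcripts took 26.3% to 27.8%. The number of sequenced fragments is unknown, because whole reads could not be recovered from the FPKM values. Pearson correlations of log2 values across genes, which are not independent replicates, were 0.989 to 0.991 within groups and 0.974 to 0.976 between groups. The first principal component carried 57.7% of the variance.

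The siRNA target was lower in all 3 libraries of its group. DYRK2 (ENSG00000127334; GRCh38 chromosome 12, 67648338 to 67665406, plus strand) stood at 5.95 ± 0.110 FPKM (SD, n = 3) with the scramble siRNA and at 1.49 ± 0.0451 FPKM (SD, n = 3) with siDYRK2, which is 25.1% ± 0.757 (SD, n = 3) of the scramble mean. The log2 fold change, taken as siDYRK2 minus scramble on the log2(FPKM + 0.5) scale, was −1.69 (SE 0.0513, limma adjusted p = 2.0e-06). The exact two-sided permutation test of the 6 values gave p = 0.1, the smallest p that 3 against 3 libraries allow.

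Silencing of DYRK2 went with many small differences and few large ones. Of 15121 genes with a mean of at least 0.5 FPKM, 3079 were higher and 2714 lower in the siDYRK2 libraries by limma at an adjusted p under 0.05, together 38.3% of the genes tested. The median absolute log2 fold change of these genes was 0.32, and only 60 of the higher and 124 of the lower genes had an absolute log2 fold change of at least 1 on the log2(FPKM + 0.5) scale. The FPKM of the 2 groups did not overlap for 51.7% of the tested genes, against 10% by chance. Fold changes on this scale understate the change of genes with low values.

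Of the 10 largest increases, ANGPTL4 came first. ANGPTL4, which encodes a secreted inhibitor of lipoprotein lipase, rose 7.69-fold from 11.2 ± 0.638 to 85.9 ± 12.8 FPKM (SD, n = 3). The ID genes encode inhibitors of basic helix-loop-helix transcription factors. ID3 rose 6.74-fold to 69.6 ± 3.08 FPKM and ID1 rose 6.46-fold to 98.7 ± 5.38 FPKM (SD, n = 3). ANKRD1, a known target of YAP, rose 4.65-fold, and PER1, a component of the circadian clock, rose 5.22-fold. HMOX1, the inducible haem oxygenase, rose 3.25-fold to 39.4 FPKM, and PDK4, an inhibitor of pyruvate dehydrogenase, rose 3.83-fold to 4.21 FPKM. SELENOH, SECTM1 and CYP24A1, the last encoding the vitamin D 24-hydroxylase, completed the 10 largest increases, at 3.21-fold, 3.13-fold and 2.93-fold. Limma adjusted p for these 10 genes lay between 2.7e-07 (ID3) and 0.0013 (SELENOH).

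Among the 10 largest decreases, F13A1, the A subunit of coagulation factor XIII, dropped from 6.2 ± 0.668 to 0.18 ± 0.0265 FPKM (SD, n = 3). INSIG1, which retains the SREBP precursor in the endoplasmic reticulum, fell 6.59-fold from 44.8 ± 1.82 to 6.79 ± 0.125 FPKM (SD, n = 3). OAT (GRCh38 chromosome 10, 124397303 to 124418976, minus strand), the mitochondrial ornithine aminotransferase, fell from 57.8 ± 2.18 to 9.33 ± 0.155 FPKM (SD, n = 3). SCD, the stearoyl-CoA desaturase, fell 3.70-fold from 517 to 140 FPKM. FGFBP1 fell 10.2-fold, LCN2 5.05-fold and BHLHE40 5.15-fold. A pair of pseudogenes, RPL31P11 and DENND10P1, was also among the 10 largest decreases. Their reads may be shared with near-identical copies, and the fall of DENND10P1 (limma adjusted p = 0.029) lost its call in 6 of the alternative analyses. The parent gene RPL31, looked up after the values of its pseudogene were seen, stood at 21.0 and 21.8 FPKM (limma adjusted p = 0.52).

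**Figure D1:**
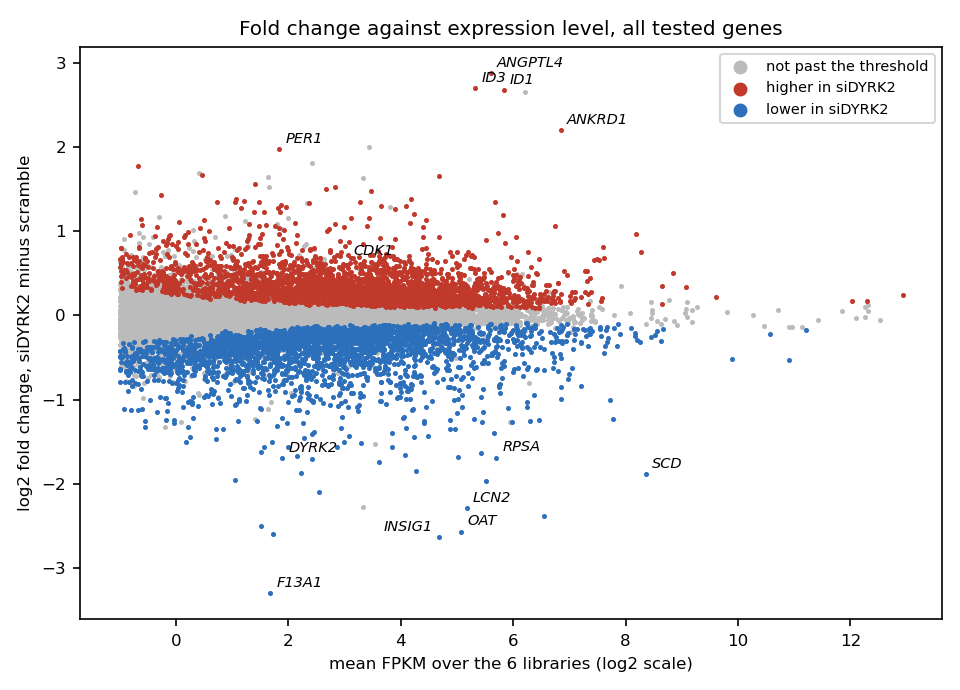
Log2 fold change (siDYRK2 minus scramble, on the log2(FPKM + 0.5) scale) against the mean FPKM over the 6 libraries on a log2 scale, 1 point per tested gene, with the 3079 higher genes in red, the 2714 lower genes in blue and the others in grey. Most coloured points lie close to 0, and the labelled genes include the largest changes, such as ANGPTL4 at 2.88 and F13A1 at −3.30.

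Transcripts with a particular short sequence in their 3′ untranslated region were lower more often than others, among them several of the genes named here. Among 15640 words of 7 bases scanned in the 3′ untranslated regions of 11636 tested genes, ATCTATA had the most negative association with the fold change (t = −12.93, 1174 genes). The DYRK2 transcript carries the 8-base word CATCTATA in its coding region. It also carries ATCTATA in its 3′ untranslated region, which is 6696 bases long. The share of genes called lower was 35.5% of the 276 genes with CATCTATA in the 3′ untranslated region and 16.4% of the 8599 genes without the inner 6 bases ATCTAT. Among the genes with large decreases, OAT has 2 copies of the 8-base word in its 3′ untranslated region, INSIG1 and SCD have 1 ATCTATA there, and LCN2 has 1 CATCTAT in the coding region. F13A1 and BHLHE40 contain only the inner 6 bases, and FGFBP1 does not contain them. Such sites were not clearly more frequent among genes called lower with a log2 fold change of −1 or below. Of 89 such genes searched, 29 contain ATCTATA or CATCTAT (32.6%), against 24.7% of all searched genes (two-sided Fisher's exact p = 0.085). Of the 276 genes 33 were called higher (11.96%), against 26.71% of the 8599 genes without ATCTAT in the 3′ untranslated region. RB1, singled out after its values were seen, has CATCTATA in its coding region and was also higher (log2 fold change 0.20, limma adjusted p = 0.016).

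Genes of DNA replication and of mitosis were higher in the siDYRK2 libraries. In the list of G1/S and DNA replication genes 38 of 40 members rose and 1, CCNE1 (cyclin E1), fell, with a median log2 fold change of 0.50. The count was also 38 higher and 1 lower when adjusted over the list alone. RRM2, the small subunit of ribonucleotide reductase, rose 2.47-fold from 8.62 ± 0.751 to 21.3 ± 0.416 FPKM (SD, n = 3), and its partner RRM1 rose 1.60-fold. MCM4, a subunit of the replicative helicase, rose 1.55-fold and DTL, a substrate receptor of the CUL4 ubiquitin ligase, 1.59-fold. By camera the list stood above the other genes (adjusted p = 1.8e-16), and not with an estimated correlation (adjusted p = 0.25).

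In the list of G2/M and mitosis genes 33 of 42 members rose, 1 fell and 8 did not pass the test, with a median log2 fold change of 0.36. Adjusted over the list alone, 34 rose and 1 fell. CDK1 (ENSG00000170312; GRCh38 chromosome 10, 60778331 to 60794852, plus strand), the kinase that drives entry into mitosis, rose 1.59-fold from 12.3 ± 0.581 to 19.5 ± 0.993 FPKM (SD, n = 3), with a log2 fold change of 0.65 (SE 0.0512, limma adjusted p = 1.2e-04). NCAPG, a condensin subunit, rose 1.69-fold, and PRC1, a spindle midzone protein, 1.43-fold, and AURKB, the Aurora B kinase, rose from 14.5 to 21.8 FPKM. Of the partners and regulators of CDK1, CCNA2 (cyclin A2) rose 1.44-fold, CDC25C 1.37-fold and PLK1 1.36-fold. CCNB2 (cyclin B2) rose 1.21-fold, a call lost in 6 of the alternative analyses. CCNB1 (cyclin B1) stood at 17.2 ± 2.27 and 18.2 ± 2.13 FPKM (SD, n = 3) and did not differ by more than the spread (log2 fold change 0.08, limma adjusted p = 0.60). Its difference was −0.0086 without scramble replicate 3 and −0.011 without siDYRK2 replicate 3. The member that fell was MAD2L1, a spindle checkpoint protein. Camera placed the list above the other genes (adjusted p = 2.9e-08), and not with an estimated correlation (adjusted p = 0.45). Scramble replicate 3 had the lowest mean log2 level of this list, 3.40 against 3.65 and 3.58 in the other 2 scramble libraries and 3.86 to 3.99 in the siDYRK2 libraries. Without it the median log2 fold change was 0.29.

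The p53 targets went both ways. Of 24 tested members 5 rose and 8 fell, or 6 and 8 adjusted over the list alone, and the list did not stand apart by camera (adjusted p = 0.28), but was past the threshold by fry (adjusted p = 0.017). SFN (14-3-3 sigma) fell 1.59-fold, the pro-apoptotic BBC3 1.65-fold, PHLDA3 1.37-fold and PLK2 1.30-fold. CDKN1A, which encodes the CDK inhibitor p21, stood at 40.6 ± 3.66 and 38.5 ± 1.49 FPKM (SD, n = 3; log2 fold change −0.07, limma adjusted p = 0.43), and its difference was 0.0017 without scramble replicate 3.

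**Figure D2:**
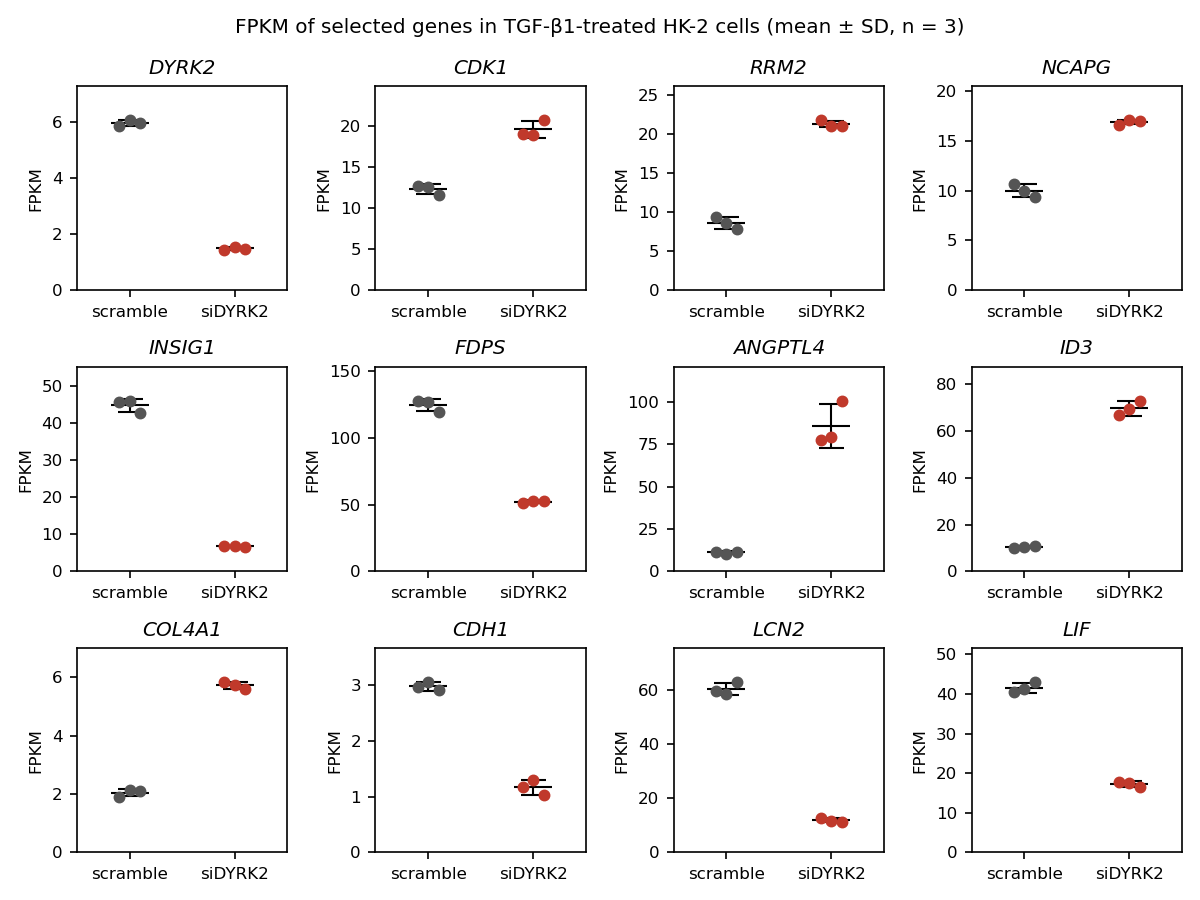
FPKM of 12 genes in each library, with the scramble siRNA in grey and siDYRK2 in red; the bars give the mean ± SD of 3 libraries and every axis starts at 0. The 2 groups do not overlap in any panel, and DYRK2 lies at 5.95 against 1.49 FPKM.

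Genes of the cholesterol synthesis list fell as a group. All 19 tested members of the list were lower, also when adjusted over the list alone, with log2 fold changes from −2.63 to −0.43 and a median of −1.25. Besides INSIG1, FDPS, the farnesyl diphosphate synthase, fell 2.39-fold from 125 ± 4.62 to 52.2 ± 1.01 FPKM (SD, n = 3), and CYP51A1, the lanosterol demethylase, fell 2.05-fold from 102 to 49.6 FPKM. The list had the smallest camera p of the 19 lists (adjusted p = 2.2e-17), and was not past the threshold with an estimated correlation (adjusted p = 0.25). The 12 members without ATCTAT in their transcript were all lower, with a median log2 fold change of −1.12.

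Extracellular matrix genes that passed the test were mostly higher. Of the 40 members of the matrix list 24 were tested, 12 were below the expression filter and 4 had no row. Of 24 tested matrix genes 14 rose and 4 fell, overall and adjusted over the list alone, with a median log2 fold change of 0.30. COL4A1, a basement membrane collagen chain, rose 2.81-fold from 2.04 ± 0.119 to 5.71 ± 0.120 FPKM (SD, n = 3). The collagen cross-linking enzyme LOXL2 rose 1.70-fold and THBS1, the matrix glycoprotein thrombospondin 1, 1.77-fold. The cross-linking transglutaminase TGM2 fell 1.99-fold from 155 to 77.6 FPKM. The other members that fell, named after their values were seen, were LAMB3 (from 226 to 166 FPKM), LAMA3 and TNC. FN1 (fibronectin) stood at 2.37 ± 0.114 and 2.48 ± 0.0493 FPKM (SD, n = 3; limma adjusted p = 0.53). COL1A1 was below the expression filter at 0.347 ± 0.0208 and 0.570 ± 0.0557 FPKM (SD, n = 3) and was not tested. By camera the list stood above the other genes (adjusted p = 0.0014), and not with an estimated correlation (adjusted p = 0.25).

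In the mesenchymal and contractile list 6 of 14 tested members rose and 1 fell, or 6 and 2 adjusted over the list alone. SNAI2, a transcriptional repressor of epithelial genes, rose 3.22-fold from 0.983 ± 0.458 to 3.16 ± 0.191 FPKM (SD, n = 3), and its relative SNAI1 rose 1.97-fold. TAGLN (transgelin) rose 2.22-fold and ITGA5, the fibronectin receptor subunit, 1.92-fold. VIM (vimentin) was 1.11-fold lower (limma adjusted p = 0.044), a call lost in 9 of the alternative analyses. ACTA2, the smooth muscle actin, was below the filter at 0.203 ± 0.0231 and 0.197 ± 0.0404 FPKM (SD, n = 3). The list missed the camera threshold (adjusted p = 0.069), but was past it when low values were not filtered (adjusted p = 0.041) and by fry (adjusted p = 3.7e-04).

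In the epithelial junction list 11 of 19 tested members fell, 1 rose and 7 did not pass the test, overall and adjusted over the list alone, with a median log2 fold change of −0.26. The median was −0.19 for the 13 members without ATCTAT in their transcript. CDH1 (E-cadherin) fell 2.55-fold from 2.97 ± 0.0751 to 1.17 ± 0.131 FPKM (SD, n = 3; limma adjusted p = 8.4e-05). CD24 fell 1.90-fold, KRT19 1.62-fold and KRT18 1.41-fold. By camera the list stood below the other genes (adjusted p = 7.5e-04), and not with an estimated correlation (adjusted p = 0.25).

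The TGF-β/SMAD targets did not move in one direction. Of 25 tested members 8 rose and 10 fell, or 9 and 12 adjusted over the list alone. The median log2 fold change was −0.05, the mean was 0.08, and camera gave an adjusted p of 0.72. TGFBI, a matrix protein induced by TGF-β, rose 2.54-fold from 9.68 to 24.6 FPKM, alongside ANGPTL4. CCN2 (connective tissue growth factor) rose 1.37-fold from 37.3 ± 1.54 to 50.9 ± 2.62 FPKM (SD, n = 3; limma adjusted p = 4.7e-04). LTBP3, a latent TGF-β binding protein, fell 1.80-fold, alongside the transcriptional repressor BHLHE40. Camera gave the direction as down and fry as up, and neither these nor any alternative put the list past the threshold (adjusted p from 0.46 to 0.89). TGFBR2, a TGF-β receptor, and SMAD2 and SMAD3, which carry its signal, were singled out after their values were seen. They fell with log2 fold changes of −0.49, −0.42 and −0.43. SMAD4 also fell (−0.21, limma adjusted p = 0.018), while TGFBR1 was not called (−0.12, limma adjusted p = 0.081). The 3′ untranslated regions of TGFBR2 and SMAD2 contain ATCTATA and that of SMAD3 CATCTAT. Those of SMAD2 and SMAD3 are 10279 and 4662 bases long. Of all searched genes 24.7% contain ATCTATA or CATCTAT anywhere in their transcript. Counted in the 3′ untranslated region alone, 276 of 11636 genes contain CATCTATA, a further 898 ATCTATA and a further 561 CATCTAT.

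**Figure D3:**
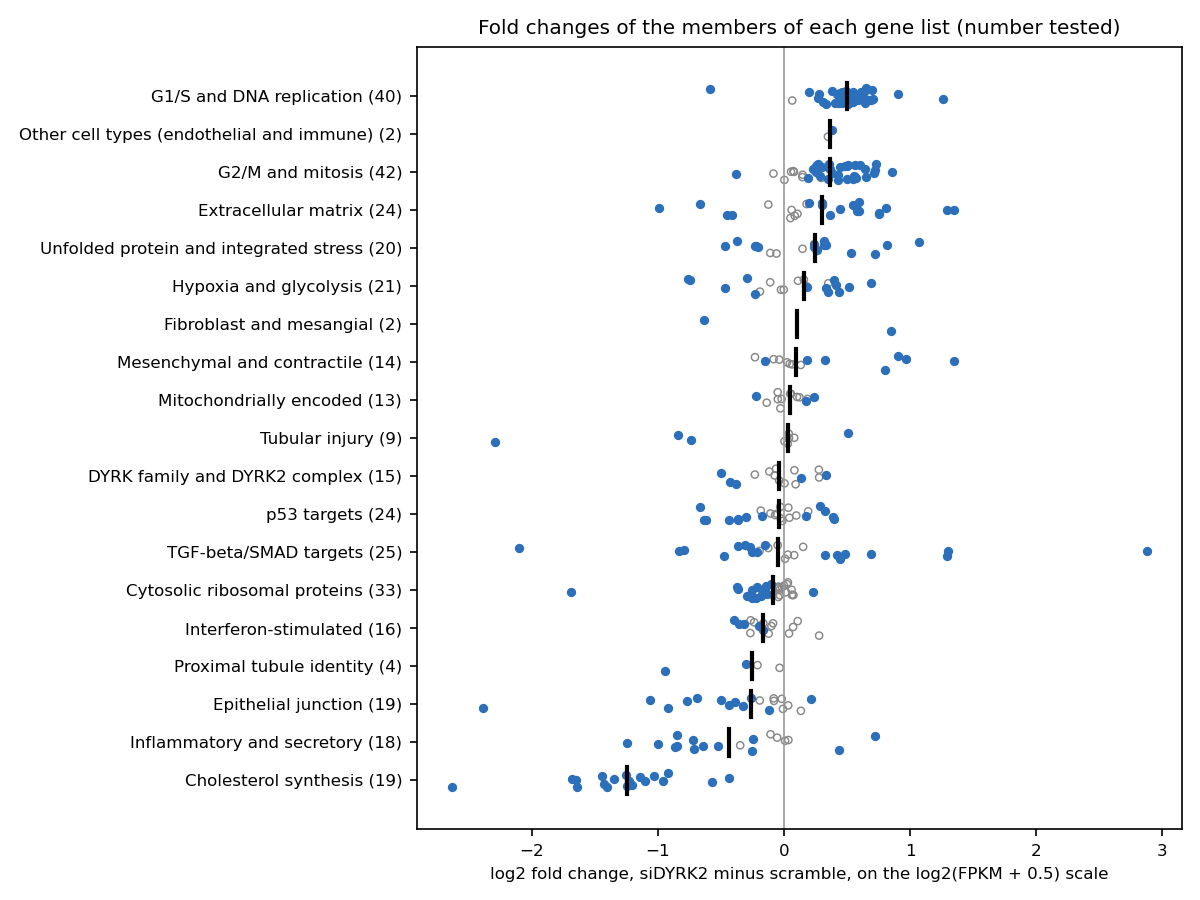
Log2 fold change of each tested member of the 19 gene lists (siDYRK2 minus scramble, on the log2(FPKM + 0.5) scale), with filled points for members at a limma adjusted p under 0.05, open points for the others and a black bar at the median of the list. The cholesterol synthesis list lies lowest with a median of −1.25 and the G1/S and DNA replication list highest with a median of 0.50.

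Most proximal tubule genes were at low levels in both groups. Of the 26 members of the proximal tubule list 4 had a mean of at least 0.5 FPKM, 16 were below that level and 6 had no row in the table. FBP1, a gluconeogenic enzyme, fell 2.04-fold from 6.95 to 3.40 FPKM. In all, 2 of the 4 tested members fell and 0 rose, overall and adjusted over the list alone. The list was past the camera threshold (adjusted p = 0.038) and was not with an estimated correlation (adjusted p = 0.25). Its call was also lost under 6 other alternatives, with the highest adjusted p, 0.29, when low values were not filtered, and with 0.0502 without siDYRK2 replicate 1. NKX2-1, a transcription factor of lung and thyroid epithelium singled out after its values were seen, stood at 26.5 ± 0.895 and 23.4 ± 0.472 FPKM (SD, n = 3), while the renal factor PAX8 stood at 0.183 ± 0.00577 and 0.0867 ± 0.00577 FPKM (SD, n = 3).

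Among the tubular injury genes 3 of 9 tested members fell and 1 rose, overall and adjusted over the list alone. LCN2, the injury marker also known as NGAL, fell 5.05-fold from 60.3 ± 2.25 to 11.9 ± 0.726 FPKM (SD, n = 3; limma adjusted p = 8.6e-07). SOX9, a factor of injured tubule cells, fell 1.92-fold and CLU (clusterin) 1.68-fold. KRT7 (keratin 7) rose 1.42-fold from 382 to 542 FPKM. HAVCR1, the injury marker KIM-1, was listed at no more than 0.01 FPKM in any library and was not tested. The median log2 fold change was 0.03 and the mean −0.35, and camera did not set the list apart (direction down, adjusted p = 0.40), whereas by fry it was past the threshold (adjusted p = 1.6e-04).

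Inflammatory and secreted factors were mostly lower. Of 18 tested members 11 fell and 2 rose, or 12 and 2 adjusted over the list alone, with a median log2 fold change of −0.43. The median was −0.26 for the 15 members without ATCTAT in their transcript. LIF, a cytokine of the interleukin 6 family, fell 2.41-fold from 41.6 ± 1.29 to 17.3 ± 0.667 FPKM (SD, n = 3). The collagenase MMP1 fell 2.01-fold from 281 to 140 FPKM, the chemokine CXCL2 1.82-fold, and the EGF receptor ligand EREG 1.84-fold. The members that rose were CCL20, a chemokine, and NFKBIA, the inhibitor of NF-κB, and were named after their values were seen. The list lay below the other genes by camera (adjusted p = 6.9e-04), and not with an estimated correlation (adjusted p = 0.34).

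Interferon-stimulated genes differed little. Of 16 tested members 5 were lower and none higher over all genes tested, and 0 in either direction adjusted over the list alone. IFIT3 was 1.37-fold, OASL 1.73-fold, STAT2 1.15-fold and HERC5 1.14-fold lower, and each of these calls was lost in at least 5 alternative analyses. The list passed the camera threshold (adjusted p = 0.043) and did not with an estimated correlation (adjusted p = 0.52). Leaving out 1 library ended the call for scramble replicate 1 (adjusted p = 0.064), scramble replicate 2 (0.085), scramble replicate 3 (0.0507) and siDYRK2 replicate 3 (0.11). The call was also lost with a filter of 2 FPKM (0.092), after quantile normalization (0.057), with the replicate block (0.053) and by fry (0.074). Over all alternatives at the preset correlation or by fry the adjusted p ranged from 0.020 to 0.11.

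In the list of the unfolded protein and integrated stress responses 11 of 20 members rose and 5 fell, or 13 and 6 adjusted over the list alone. The chaperones CALR (calreticulin) and HSPA5 (BiP) rose 1.76-fold and 1.45-fold, ASNS (asparagine synthetase) rose 2.10-fold from 69.1 to 145 FPKM, and the serine synthesis enzyme PSAT1 rose 1.26-fold. The members that fell, named after their values were seen, were ATF3, TRIB3, XBP1, DDIT4 and DDIT3, most of them transcription factors of these responses or their targets. Camera gave an adjusted p of 0.038 for the list of unfolded protein and integrated stress genes, a call lost under 7 alternatives. The adjusted p was 0.25 with an estimated correlation, 0.077 without siDYRK2 replicate 3, 0.068 with a filter of 2 FPKM, 0.057 after quantile normalization and 0.056 with the replicate number as a block. It was 0.085 with only genes searched for ATCTAT and 0.54, the highest, with only those of them without it.

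Hypoxia and glycolysis genes went both ways, with 8 of 21 tested members higher and 5 lower, or 9 and 5 adjusted over the list alone (camera adjusted p = 0.48). The glucose transporter SLC2A1 fell 1.71-fold and VEGFA 1.69-fold, whereas PFKFB3, a regulator of glycolysis, rose 1.66-fold and HK1 (hexokinase 1) rose 1.33-fold.

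Of the 33 cytosolic ribosomal protein genes 15 were lower, 1 was higher and 17 did not pass the test, overall and adjusted over the list alone, with a median log2 fold change of −0.09. For the 23 members without ATCTAT in their transcript the median was −0.04. Camera gave an adjusted p of 0.0041, and 0.45 with an estimated correlation. RPSA (GRCh38 chromosome 3, 39406689 to 39412542, plus strand), a protein of the small ribosomal subunit, stood apart from the list. It fell 3.27-fold from 79.7 ± 2.22 to 24.4 ± 1.31 FPKM (SD, n = 3), and its coding region carries 2 copies of CATCTATA. Reads of RPSA may be shared with its near-identical copies, and 8 of the 9 tested family members, RPSA included, were lower. RPL13A fell 1.29-fold, RPL4 1.22-fold and RPS18 1.19-fold, the call of RPL4 being lost after quantile normalization.

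Of the 13 mitochondrially encoded genes 2 were higher and 1 lower, overall and adjusted over the list alone (camera adjusted p = 0.60). MT-CO1 was 1.18-fold and MT-ND1 1.13-fold higher and MT-ND6 1.17-fold lower, and each of these calls was lost in at least 2 alternative analyses. Of the 15 members of the DYRK family and DYRK2 complex list 2 rose and 3 fell, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.66). HIPK1, a related kinase, fell 1.38-fold, JUN, a substrate of DYRK2, fell 1.42-fold, and DYRK3 fell 1.37-fold, the last call being lost in 3 alternative analyses.

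Markers of other kidney cell types were low. Of 20 endothelial and immune genes 2 had a mean of at least 0.5 FPKM, and of these CD74 rose 1.40-fold from 1.54 to 2.15 FPKM (camera adjusted p of the list = 0.20). That list was past the threshold after rescaling to a common sum (adjusted p = 0.044), by fry (0.011) and without scramble replicate 3 (0.028). The rescaling raised all values against an unchanged filter, so genes with lower values were also tested. Of 14 fibroblast and mesangial genes 2 were tested, and CSPG4 rose 2.54-fold from 0.540 to 1.37 FPKM while RGS5 fell 2.16-fold from 0.967 to 0.447 FPKM (camera adjusted p = 0.91). In both lists the counts were the same adjusted over the list alone.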

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

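The alternatives with only genes searched for ATCTAT, and with only those of them without it, were chosen after the data had been seen and the others before. DYRK2 was lower in every fit that included it, with log2 fold changes from −1.93 to −1.48. The counts of 3079 higher and 2714 lower genes stayed within 1.5 times under other pseudocounts, filters, scalings and fits, and ranged from 2332 to 2728 and from 2099 to 2367 when 1 library was left out. With only the 11901 searched genes they were 3246 and 2436, and with only the 7125 searched genes without ATCTAT 2025 and 1198, the higher share being 57.1% and 62.8% against 53.2%. They were 60 and 124 at an absolute log2 fold change of at least 1, by construction fewer. With an estimated correlation the adjusted p rose to 0.45 for the G2/M list and to 0.25 for the G1/S and extracellular matrix lists. In the G2/M list that correlation was 0.67, so many members add little independent evidence. The direction of the TGF-β/SMAD list turned to up by fry (0.59) and with only searched genes without ATCTAT (0.77). The direction of the fibroblast list, with 2 tested genes at the preset filter, turned after rescaling to a common sum (0.84). That rescaling raised all values against an unchanged filter and pseudocount, so 19959 genes were tested against 15121. It thus acted largely as a lower filter and pseudocount, and not only as a change of scaling between libraries. The cause of neither turn was tested further. Leaving out 1 library gave log2 fold changes from −0.011 to 0.17 for CCNB1 and from −0.11 to 0.0017 for CDKN1A, neither called, the turns coming without scramble replicate 3 (both genes) or siDYRK2 replicate 3 (CCNB1). Of 92 called named genes 79 kept their call in every fit that included them, 13 lost it in at least 1, and 0 changed sign. No pairing by replicate number was visible in the values, since deviations of same-numbered libraries correlated at −0.077, 0.024 and −0.088 across genes. These correlations do not show whether same-numbered libraries were made together. With the number as a replicate block 2495 genes were higher and 2321 lower. Planned count models were not run because counts could not be recovered, so what depth limits is unknown. The self-test, which called 18% of genes at a log2 fold change of 0.25, did not vary depth. It also changed far fewer genes than the real comparison called.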

Other observations

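The tests of short sequence words (except the coding-region sites), shared reads, sites in sterol transcripts, lung-type transcripts, PPAR targets and glucocorticoid targets were chosen after the results they concern had been seen. The tests of coding-region sites, of scaling and of other splits were chosen before, although the sites in RPSA were already known. Lists in this part were written after the fold changes had been seen, so their counts do not test their direction independently.

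Genes of fatty acid synthesis fell along with those of cholesterol synthesis, and several genes of fatty acid oxidation and storage rose. Of 12 fatty acid synthesis genes 10 fell and 1 rose, with a median log2 fold change of −0.63. FASN, the fatty acid synthase, fell from 89.1 ± 3.36 to 36.7 ± 0.292 FPKM, FADS2 from 61.9 ± 1.47 to 25.4 ± 0.366 FPKM and ACSS2 from 24.7 ± 1.37 to 9.44 ± 0.246 FPKM (SD, n = 3). In the opposite direction, ACADVL, the mitochondrial very long-chain acyl-CoA dehydrogenase, rose from 45.3 ± 1.14 to 87.0 ± 1.25 FPKM, the carnitine carrier SLC25A20 from 2.01 ± 0.145 to 4.75 ± 0.114 FPKM and the lipid droplet protein PLIN2 from 13.6 ± 0.674 to 28.6 ± 1.14 FPKM (SD, n = 3). With ANGPTL4 and PDK4 these are known targets of PPAR receptors, so a PPAR response is a hypothesis. Of the 9 targets seen beforehand 6 rose. Of 12 further tested targets whose values had not been seen 3 rose and 0 fell (median log2 fold change 0.12, limma camera adjusted p = 0.14 over this list and the next one tested in this way), so the further genes leave it open.

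All 6 tested genes of the BMP and ID list were higher, with a median log2 fold change of 0.93. Beside ID1 and ID3, ID2 rose from 0.697 ± 0.0850 to 2.12 ± 0.130 FPKM and SMAD9, a receptor-regulated SMAD of BMP signalling, from 1.55 ± 0.174 to 2.90 ± 0.118 FPKM (SD, n = 3). Another set that rose holds known glucocorticoid-induced genes. FKBP5 rose from 13.5 ± 0.560 to 30.2 ± 1.24 FPKM and KLF9 from 1.84 ± 0.0200 to 5.17 ± 0.181 FPKM (SD, n = 3), and ZBTB16, below the filter, stood at 0.0333 ± 0.00577 and 0.873 ± 0.0473 FPKM (SD, n = 3). All 7 tested genes of this set seen beforehand rose. A glucocorticoid response may be one source, but of 14 further tested targets 4 rose and 5 fell (median log2 fold change −0.04, limma camera adjusted p = 0.50). The 4 that rose include MT2A (0.97) and TFCP2L1 (0.61), and the 5 that fell include CRISPLD2 (−1.47) and SPSB1 (−0.86). A median at or below 0 was the outcome set against this response. It lies well within the spread of these genes, so the response stays open, but the further targets did not rise as a set.

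The fall of transcripts with ATCTATA may reflect the siRNA acting on transcripts other than DYRK2 through the seed of its guide strand, whose sequence was not used here, or a response to lower DYRK2, and no second siRNA was analysed here. The base composition or length of the 3′ untranslated regions is argued against as the whole cause, because the 139 tested rearrangements of the same bases had a median t of −1.04 against −12.93. The lowest t of the 137 that share no 6 bases in a row with ATCTATA was −5.35. The other 2, AATCTAT (−7.14) and TCTATAA (−5.62), hold 6 of its bases in a row and so do not separate the word from its composition. The lowest t among words that share no 5 bases with CATCTATA was −4.25. Genes with CATCTATA in the coding region and no ATCTAT in the 3′ untranslated region (154) had a mean log2 fold change 0.09 lower than the 8445 others (difference −0.092, one-sided permutation p = 1.2e-04; −0.082 without RPSA). A seed effect would give such a difference. However, this comparison did not adjust for the length or base composition of the coding region and used no rearranged words. It therefore does not separate the word from these properties. For RPSA, shared reads as the whole cause are argued against, because the summed FPKM of its 9 family members fell by 1.75 on the log2 scale. Sites were not clearly more frequent among genes called lower with a log2 fold change of −1 or below on the log2(FPKM + 0.5) scale, of which 29 of 89 searched contain a 7-base word of the pair against 24.7% of all searched genes (two-sided Fisher's exact p = 0.085). Of the 53 searched genes called higher with a log2 fold change of at least 1, 8 contain such a word (15.1%, not tested), which is the direction a seed effect would give.

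Direct seed sites do not account for the whole fall of the cholesterol synthesis genes, since the 12 members without ATCTAT fell with a median log2 fold change of −1.12. Scaling between libraries is argued against by the median of −1.26 under median-ratio scaling. For the 7 members with ATCTAT an added direct effect stays open, since their mean was lower than that of the other 12 (difference −0.50, exact two-sided permutation p = 0.014). An effect of the siRNA on an upstream regulator of these genes and an effect of lower DYRK2 were not tested and stay open.

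Lung-type transcripts were present at levels that most proximal tubule transcripts did not reach. Of 20 lung epithelium genes 8 had a mean of at least 1 FPKM, against 2 of 26 proximal tubule genes (two-sided Fisher's exact p = 0.012), with LAMP3 at 17.3 ± 0.899, FOXA1 at 15.6 ± 1.06, ABCA3 at 9.26 ± 0.257, SFTA3 at 8.08 ± 0.326 and SFTPB at 3.65 ± 0.729 FPKM in the scramble libraries (SD, n = 3). The lung list was written after the data had been seen and the proximal tubule list before, so this p does not test the difference independently. A candidate explanation is that the cultures hold cells of another origin, although SFTPC, among the most abundant transcripts of alveolar cells, stood at 0.0200 FPKM, MUC1 is also known in renal epithelium, and no reference library of HK-2 cells was analysed here. Of 10 thyroid epithelium genes 1, FOXE1, reached 1 FPKM. A difference in the share of such cells between the groups stays open. The median absolute log2 fold change of the 8 tested lung genes was 0.15, 3 of them (NAPSA, FOXA1 and AGER) were lower and 1 (ABCA3) was higher.

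The 6 libraries can be divided into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real division gave 3079 higher and 2714 lower genes, the highest count in either direction of any other division being 2, and 1 of the 10 divisions, the real one, gave as many. For gene lists past the camera threshold the real division gave 10 and the others 2 to 7, again 1 of the 10 giving as many. Camera at the preset correlation passed some lists in every division that mixed the groups. Each of those divisions sets unequal numbers of siDYRK2 libraries against each other, so part of the siRNA difference remains in it. The mixing also widens the spread within its groups, which lowers the count of genes called. The mixed divisions therefore do not show what would pass without an siRNA difference. They also do not tie a list that passes to the siRNA.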
